A study of Mus musculus with 13 samples.

How the data were processed

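Jejunal epithelial cells were sorted by flow cytometry and their polyadenylated RNA was sequenced, per the labels' protocols. The table used here was deposited by the authors as raw counts per gene, whole numbers with no normalization, for 21868 gene symbols in 13 libraries. Genome builds GRCm38 and mm10 and the tools FastQC 0.11.8, cutadapt 2.9, STAR 2.7.2e and DESeq2 1.32.0 are named per the submitters' processing notes, without their settings. The annotation, the strand setting and the rule for reads that map to several genes were not given in the sources used here, so genes with near-identical copies, and genes that overlap on opposite strands, are uncertain. Of the symbols, 21689 (99.2%) matched GENCODE release M21 on GRCm38, from which identifiers and coordinates were taken. Of the matched symbols, 21676 were annotated as protein coding. Library totals ranged from 4851239 to 5202146 counts in the control group and from 7127769 to 8589351 in the others. A floor of 3 counts, summed over a group, corresponds to 0.214 CPM in con, 0.183 in BSF, 0.121 in BSF_C, 0.127 in LSF and 0.197 in DSF, and floors and counting intervals cover counting error only. Where a group had no count, the fold is given as a lower bound against that floor. With 1 to 3 counts, the ratio is given with its exact 95% interval.

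Groups followed the labels: con (3 libraries), BSF (2), BSF_C (3), LSF (3) and DSF (2). The labels number the DSF replicates 1 and 2, but the columns are marked S2 and S3, so DSF libraries were given no replicate number. Genes were kept by edgeR's filterByExpr with group (14300 genes, 99.91% of counts), and libraries were scaled by trimmed means (TMM) in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood test was run in 1 fit of all 13 libraries with group as the only term (8 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE printed with a log2 fold change was that change, without its sign, over the square root of the F of this test. It is not the standard error of the fitted coefficient and can be too small where a group had few counts. The biological coefficient of variation was 4.9% in common and 6.2% for the median gene. The planned comparisons were BSF, BSF_C, LSF and DSF each against con, BSF_C against BSF, and BSF against the mean of LSF and DSF. The tests, the 6 comparisons, the alternatives listed first below, the 43 gene lists and the rule for named genes were chosen before the data were examined. LSF against DSF and the 10 lists of other tissues were added afterwards.

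Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over all lists and the 6 planned comparisons together, and separately for LSF against DSF. Each was also tested with an estimated correlation and with fry. Fold changes of comparisons that share con were set beside 20 simulations of unchanged groups, with con itself drawn anew from its means, and beside the overlap of independent lists. Genes were named by a rule. Per comparison it took the 6 called genes with the largest rise and the 6 with the largest fall among those with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out mitochondrially encoded genes and unnamed gene models. It also took up to 3 members with the smallest p of each list that passed or held at least 3 called members, and Arntl, Per2, Nr1d1, Dbp, H2-Ab1, Cd74, Epcam and Ptprc in every comparison. Some genes taken by this rule are not reported here. Genes of the other-tissue lists were chosen after their values were seen.

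The procedure was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. For BSF against con (14158 genes) 60% and 78% were recovered with 10 false calls (6.8% of calls), for BSF_C against BSF (14132 genes) 58% and 80% with 8 (5.5%), and for BSF against the mean of LSF and DSF (14133 genes) 67% and 83% with 6 (3.8%). Only those genes differed between the groups compared, as many up as down. The rates of false calls need not carry over to the real comparisons with con, where most genes were called. In a simulated list shift, camera found the shifted list of 22 genes and none of the others among 43. Those lists held random genes drawn independently, so this did not test lists whose members vary together.

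The alternatives chosen in advance were the size factors of DESeq2, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, only the groups compared in the fit, a block for the replicate number, a log2 fold change of at least 1, and leaving out each library in turn. Alternatives added later were library totals alone, libraries thinned to 4851239 counts, trends of GC content and gene length removed by a lowess fit with a span of 0.3 (both known for 99.6% of tested genes), genes of non-epithelial lists left out, and con libraries left out of the fit. Reads were not analysed here, and no library or column of the table was left out. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.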

Results

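Messenger RNA was counted per gene in jejunal epithelial cells that, per the labels, were sorted from mice as EpCAM-positive and negative for CD45, CD11b, CD3 and B220. The 13 libraries fell into 5 groups. The control group (con) had 3 libraries. Breakfast skipping (BSF, fed from ZT16 to ZT24) had 2, lunch skipping (LSF, fed from ZT12 to ZT16 and from ZT20 to ZT24) had 3 and dinner skipping (DSF, fed from ZT12 to ZT20) had 2, each kept for 2 weeks. A further 3 libraries belonged to BSF_C, which the labels call the breakfast skipping pattern combined with control without saying more. The feeding times of con and BSF_C and the hour of sampling were not given in the sources used here. Total counts were 5202146, 5080795 and 4851239 in con, 7127769 and 8589351 in BSF, 7897016, 8269342 and 7793296 in BSF_C, 8385260, 7860058 and 7592112 in LSF, and 7463941 and 7339563 in DSF. Between 14688 and 14957 genes had at least 1 count in each con library, and between 16345 and 16620 in each of the others. Of the counts, 11.7% ± 0.66 (SD, n = 3) came from mitochondrially encoded genes in con, against 9.54% in BSF, 9.63% in BSF_C, 10.1% in LSF and 10.2% in DSF.

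The con libraries stood apart from all others. The first principal component carried 77.4% of the variance and placed con at 116.6 to 122.2 and the other 10 libraries at -40.9 to -29.7. The second carried 7.8% and placed BSF and BSF_C at -25.8 to -20.4, and LSF and DSF at 16.6 to 28.0. Spearman's rho across genes was at least 0.978 within each group and 0.932 to 0.939 between con and the other libraries. For pairs within a group, the chi-square per degree of freedom over genes, which is 1 for counting error alone, was 2.17 to 4.11 in con and 1.38 to 2.14 in the other groups. It was 58.3 to 84.5 between con and any other library, and 1.63 to 13.1 between libraries of different groups other than con. The labels give no batch, so a batch holding con alone cannot be told apart from the group.

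**Figure D1:**
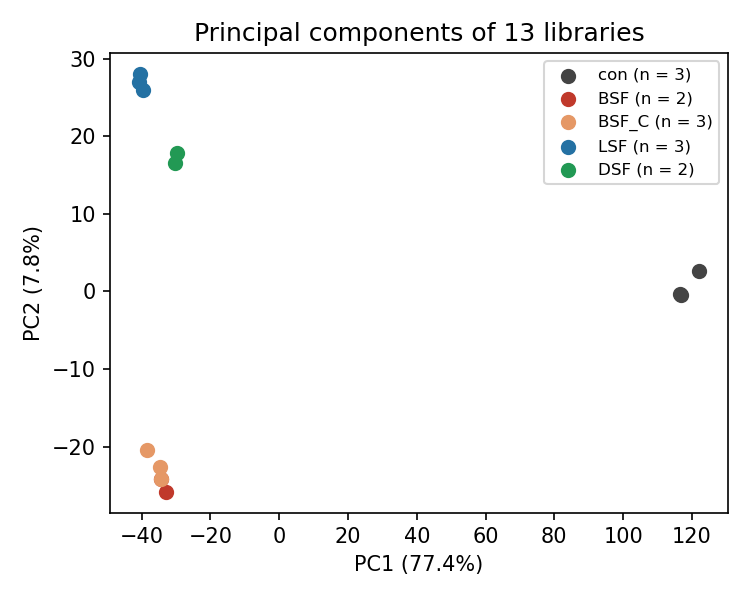
Principal components of log2 CPM for 13 libraries, with the first component on the x axis (77.4% of the variance) and the second on the y axis (7.8%), both in arbitrary units; each point is a library coloured by group. The 3 con libraries lie at 116.6 to 122.2 on the x axis and the other 10 between -40.9 and -29.7.

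Transcripts typical of other tissues differed between the groups, and they bear on every comparison with con. The lists for them were written after the data were examined. Counts of 23 skin keratinocyte genes summed to 1120 CPM in con and to 4.77, 5.74, 5.71 and 5.04 CPM in BSF, BSF_C, LSF and DSF. Calm4, a calcium-binding protein of the epidermis, was 227 ± 26.3 CPM in con (SD, n = 3) and had no count in the 10 other libraries, at least 1240-fold lower in BSF. Heart muscle genes went the other way, with sums of 131 CPM in con, 450 in BSF, 440 in BSF_C, 996 in LSF and 988 in DSF. Myh6, a myosin heavy chain of heart muscle, had no count in con and was at least 263-fold higher in BSF and at least 842-fold higher in LSF. Brain genes summed to 276 CPM in con, 465 in BSF, 480 in BSF_C, 315 in LSF and 291 in DSF. Melanocyte genes summed to 19.8, 181, 109, 206 and 178 CPM in the same order, kidney tubule genes to 14.8, 81.9, 186, 149 and 168 CPM, and fibroblast and matrix genes to 34.8, 40.4, 158, 232 and 164 CPM. Enteric neuron and glia genes summed to 10.5, 39.6, 36.7, 23.2 and 22 CPM, hepatocyte genes to 0.869, 7.85, 7.97, 6.95 and 9.1 CPM, and gut smooth muscle genes to 263, 221, 225, 219 and 234 CPM. Only 2 of 8 listed hepatocyte genes, 5 of 9 smooth muscle genes and 7 of 10 enteric genes passed the filter. Apoh made up 6.79 CPM of the hepatocyte sum in BSF. Intraepithelial lymphocyte genes summed to 87.7 CPM in con, 227 in BSF, 240 in BSF_C, 337 in LSF and 351 in DSF. Most of each con sum other than that of the skin list was a single gene or a pair: Ldb3 (117 CPM, heart), Mbp (236, brain), Pmel (17.8, melanocyte), Gpx3 (14.5, kidney), Ccn1 (25.2, fibroblast), Mylk (207, smooth muscle), Gfra3 and Ret (5.57 and 3.4, enteric), Apoh (0.869, hepatocyte) and Itgae (85.9, lymphocyte). Itgae was at 46.9 CPM in BSF, while Gzmb went from 0.36 to 51.7 CPM and Cd8a from 0.707 to 35.8 CPM, so the lymphocyte sum understates the rise of its other members. Ptprc (CD45), a surface protein of all leukocytes that the sort selected against, rose from 2 counts in the con libraries together to 13.8 ± 1.44 CPM in BSF, a ratio of 97.3 with an exact 95% counting interval of 26.6 to 808. Epcam, the antigen selected for, rose by 0.79 ± 0.06 (log2, SE) in BSF, 0.86 in BSF_C, 0.74 in LSF and 0.96 in DSF.

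**Figure D2:**
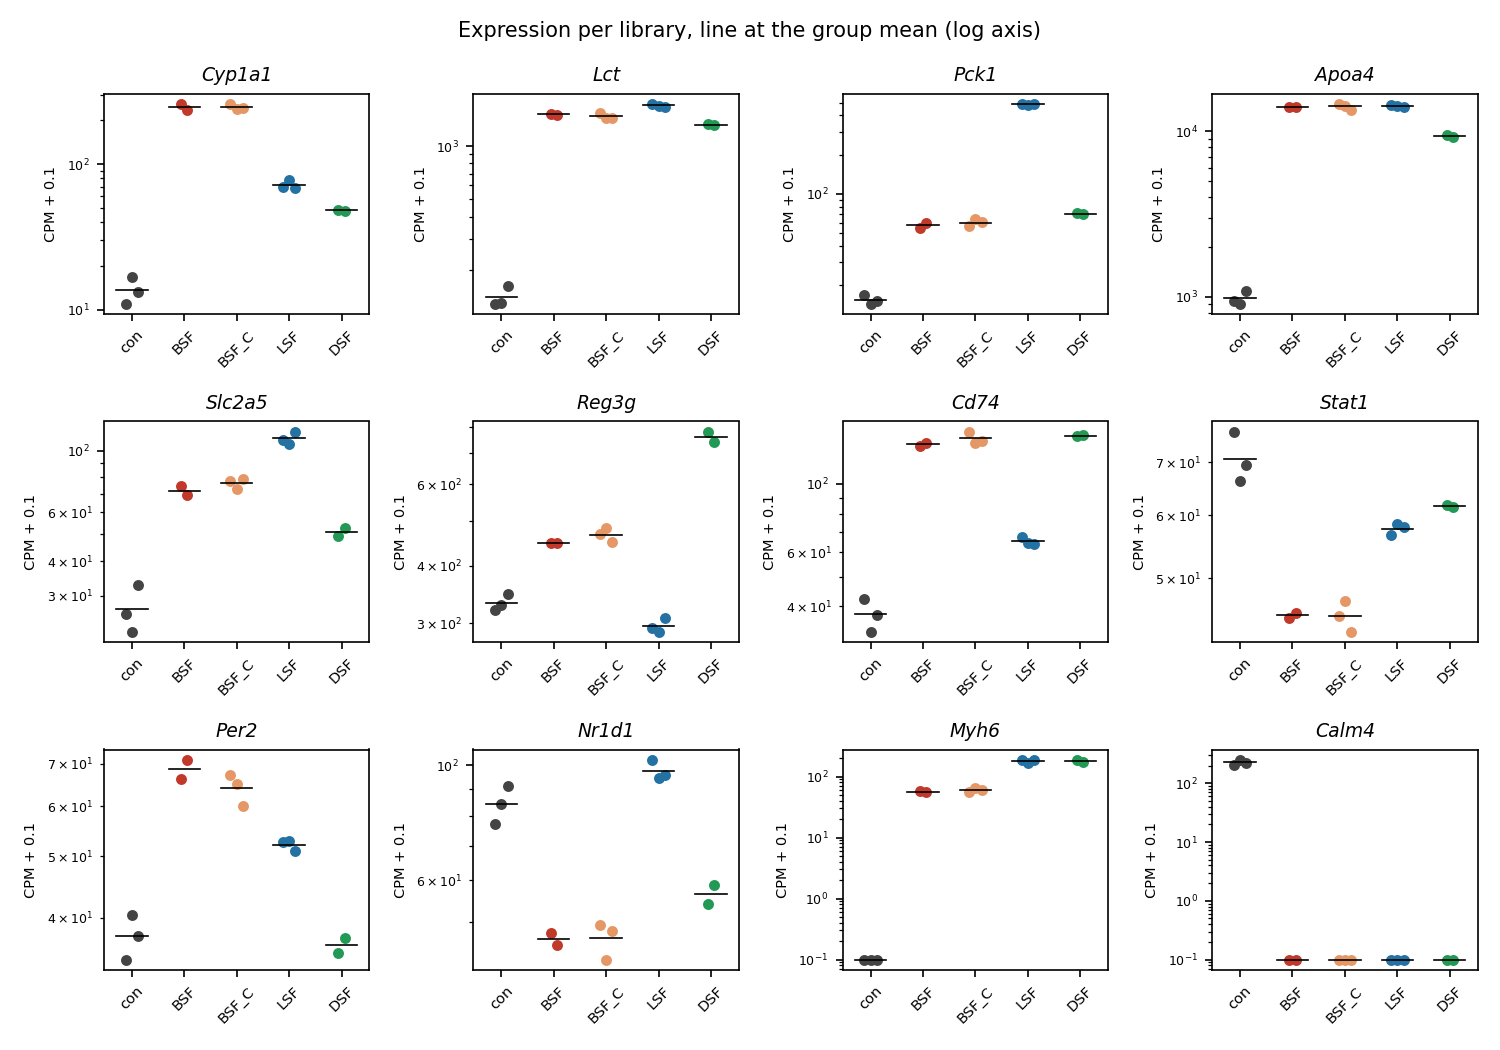
CPM plus 0.1 on a log y axis for 12 genes, with groups on the x axis, a point per library and a line at each group mean. Cyp1a1 is highest in BSF and BSF_C (247 and 248 CPM), Pck1 in LSF (489 CPM) and Reg3g in DSF (760 CPM), while Myh6 has no count in con and Calm4 none outside con.

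The comparison of BSF with con asks how the epithelium differed between 2 weeks of breakfast skipping and the control group. A batch of con cannot be told apart from feeding in this comparison. Genes for handling nutrients rose. Apoa4, an apolipoprotein packed into chylomicrons (chromosome 9, 46240696 to 46243459 in GRCm38), rose from 979 ± 96.1 to 14029 ± 23.4 CPM (SD, n = 3 and 2), a log2 fold change of 3.84 ± 0.05 (SE; adjusted p = 4.54e-51, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lct, the lactase of the brush border, rose by 3.46 ± 0.06, Slc2a2, the basolateral glucose transporter, by 2.53 ± 0.07, and G6pc, which releases free glucose, by 2.94 ± 0.10. Cyp1a1, a detoxifying oxygenase and target of the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), rose from 13.6 ± 2.87 to 247 ± 14.7 CPM (4.18 ± 0.10, adjusted p = 1.07e-39). Of 32 genes for lipid absorption and chylomicrons, 29 rose and 1 fell (camera, adjusted p = 2.06e-11, 0.026 with an estimated correlation). Among 41 xenobiotic metabolism genes, 36 rose and 1 fell (1.07e-11, 0.0145 with an estimated correlation), and among 16 genes for carbohydrate digestion and sugar transport, 15 rose and 1 fell (3.14e-07, 0.0326 with an estimated correlation). Peptide digestion and amino acid transport genes rose in 21 and fell in 3 of 26 (2.24e-06, 0.0585 with an estimated correlation). Cholesterol synthesis genes fell in 15 and rose in 3 of 25 (0.00106, 0.0706 with an estimated correlation). In each of the single genes named here both BSF libraries lay on the same side of all 3 con libraries. The naming rule favours this, as it took genes without overlap or with the smallest p of a list. Counts adjusted over the list alone were the same for these 5 lists.

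Genes of immune defence moved in several directions in BSF. Oasl2, an antiviral protein induced by interferon (chromosome 5, 114896936 to 114912234), fell from 651 ± 33.4 to 84.6 ± 4.26 CPM (-2.94 ± 0.07, adjusted p = 2.23e-39, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Oas2, a sensor of double-stranded RNA, fell by 4.29 on the log2 scale. Of 46 interferon-stimulated genes, 37 fell and 3 rose (38 and 3 adjusted over the list alone; camera, adjusted p = 7.55e-12, 0.0308 with an estimated correlation). Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652), rose from 37.6 ± 4.63 to 134 ± 2.48 CPM (1.83 ± 0.08, adjusted p = 2.75e-26), and all 8 MHC class II genes rose (0.00329, 0.0584 with an estimated correlation). Leukocyte markers rose beside them, in 21 of 30, with a median log2 fold change of 4.08, or 2.14 with genes that had no count in con at their bound (0.0213, 0.124 with an estimated correlation). Duox2, an oxidase of the apical membrane, fell by 4.40 on the log2 scale. All 13 Paneth cell genes rose (7.16e-07, 0.0585 with an estimated correlation), including the lysozyme Lyz1 by 2.26 ± 0.06 and the defensin Defa24 by 3.03 ± 0.11, whose family shares reads between near-identical members and is uncertain at the level of a single gene. Immediate early genes fell in 22 and rose in 6 of 30 (1.54e-05, 0.0901 with an estimated correlation), and Egr1, a transcription factor induced by stimulation and tissue handling, fell by 3.41 on the log2 scale. Stem cell genes fell in 14 and rose in 1 of 18, or rose in 2 adjusted over the list alone (1.75e-04, 0.0493 with an estimated correlation), among them the receptor Ephb2, which fell by 1.61.

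Core clock genes in BSF changed in part. Per2, a repressor of the clock, rose from 37.3 ± 3.03 to 68.5 ± 3.46 CPM (0.88 ± 0.09, adjusted p = 7.32e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Nr1d1, the nuclear receptor Rev-erb alpha, fell by 0.86 on the log2 scale (adjusted p = 3.02e-12). No change was called in Arntl (Bmal1), the clock's activator, at 0.04 ± 0.11 (adjusted p = 0.775), nor in Dbp, a clock output factor, at -0.10 ± 0.21 (adjusted p = 0.693). With the trends of GC content and gene length removed, Arntl was called higher, at 0.27 (adjusted p = 0.021). Neither clock list passed, each at an adjusted p of 0.547. Cytosolic ribosomal protein genes rose in 64 and fell in 3 of 79 (3.45e-11, 0.167 with an estimated correlation), nuclear-encoded oxidative phosphorylation genes rose in 58 and fell in 9 of 76 (1.05e-04, 0.0493 with an estimated correlation) and mitochondrially encoded genes fell in 9 and rose in 3 of 13 (0.00448, 0.366 with an estimated correlation). Fatty acid oxidation (0.00222), glycolysis (0.00371), proximal small intestine (0.00379), retinoid metabolism (0.0103), heat shock (0.0183), neural and glial (0.0213), MHC class I (0.0295), villus tip (0.0345), gluconeogenesis (0.0353) and stromal lists (0.0362) passed upward and barrier genes (0.00639) downward, none of them with an estimated correlation. The stromal list did not pass without con replicate 2 (0.0518) or con replicate 3 (0.0589). The lists that did not pass ranged from fatty acid synthesis (0.0639) to goblet cell genes (0.845). Median, mean and test differed in sign for antimicrobial, acinar and proliferation genes, none of which passed.

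Across all 14300 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10040 in BSF against con, 5472 higher and 4568 lower, and 4112 of them changed at least 2-fold. The median log2 fold change of all genes was 0.111, and 0.287 when libraries were scaled to their totals alone; for BSF_C, LSF and DSF against con these medians were 0.119 and 0.284, 0.1 and 0.199, and 0.101 and 0.259. Of the calls, 54.5% were higher in BSF, 54.5% in BSF_C, 54.1% in LSF and 54.0% in DSF against con, and 64.4%, 63.7%, 59.5% and 63.5% with totals alone. Of 43 lists, 19 passed upward and 6 downward, and 6 of the 25 passed with an estimated correlation. All tests were two-sided, and their p-values measure only the spread between these libraries.

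**Figure D3:**
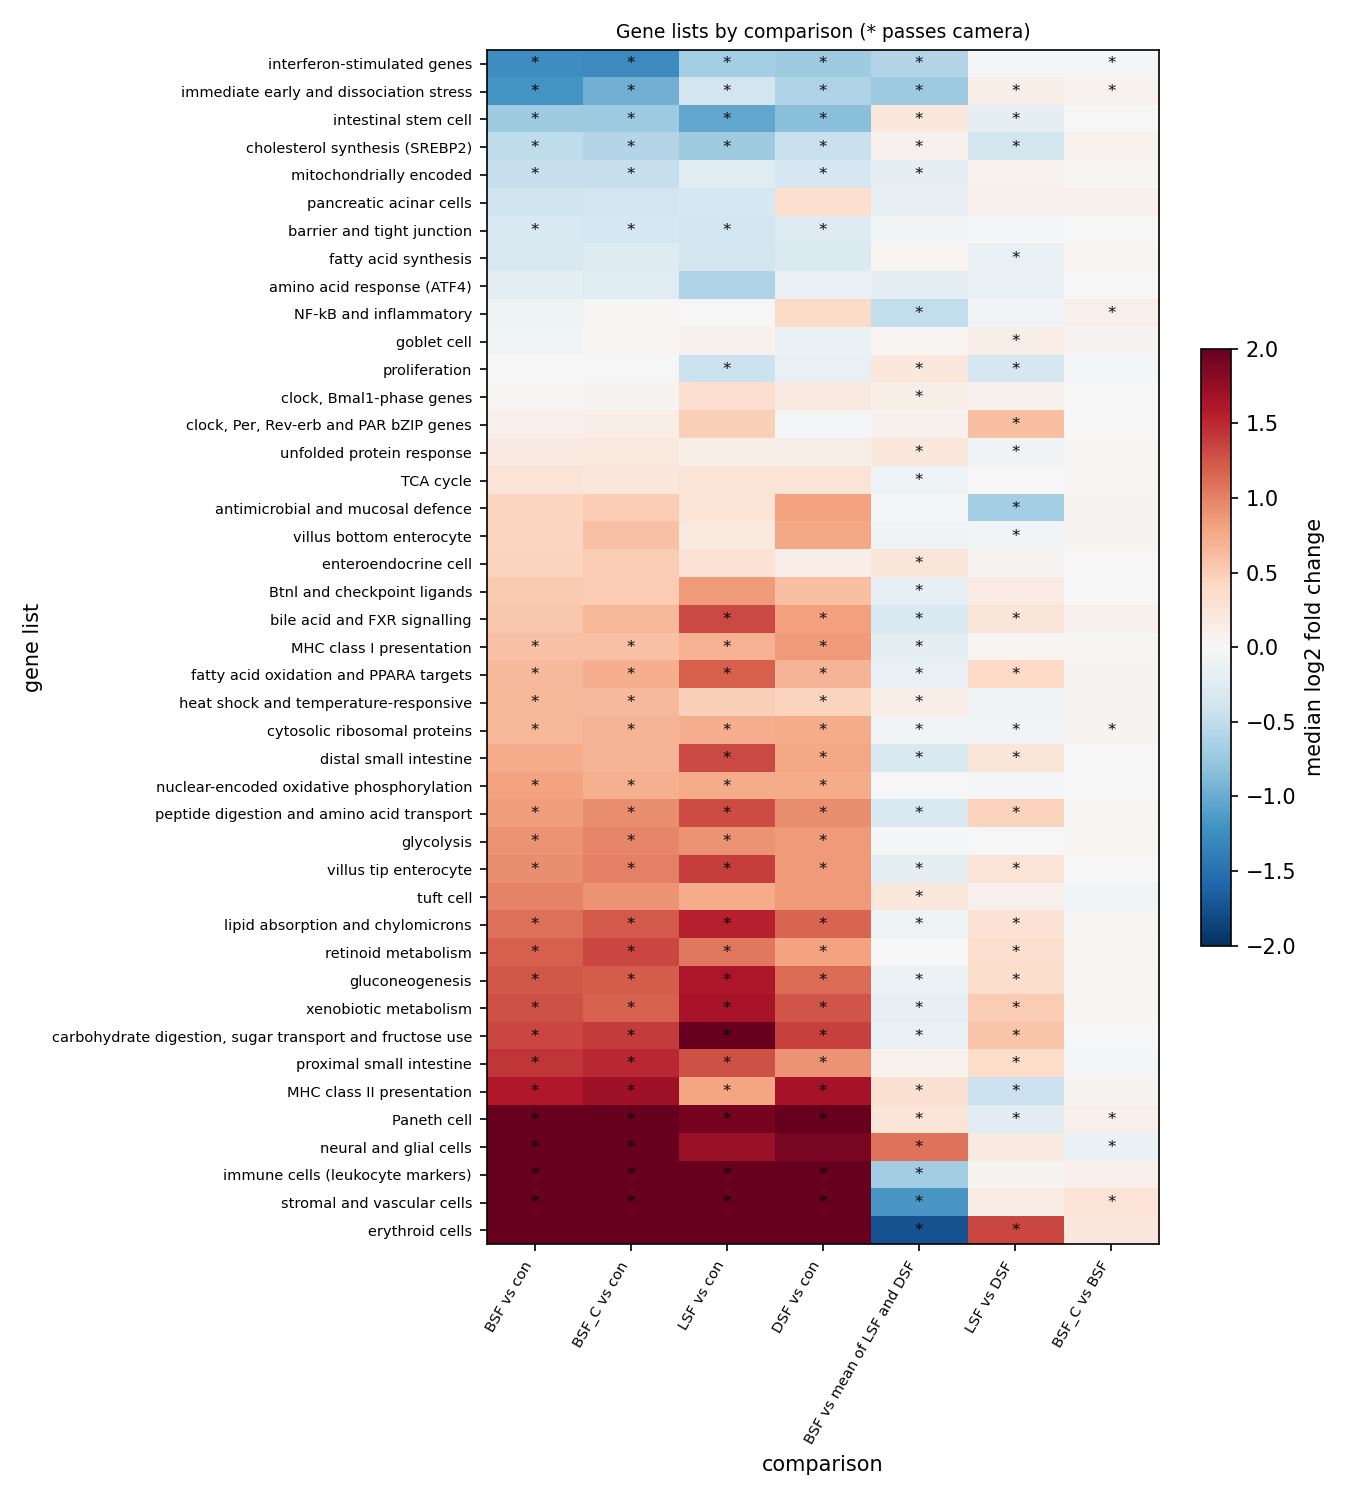
Median log2 fold change (colour, limited to -2 to 2) of 43 gene lists on the y axis in 7 comparisons on the x axis, with an asterisk where a list passed camera with the preset correlation. Interferon-stimulated genes fell in all 4 comparisons with con, and few lists stood away from 0 in BSF_C against BSF.

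The comparison of BSF_C with con asks the same of the combined group. Apoa4, the chylomicron apolipoprotein, rose by 3.86 ± 0.05 (log2, SE; n = 3 and 3), the lactase Lct by 3.42 ± 0.06 and the detoxifying oxygenase Cyp1a1 by 4.19 ± 0.09 to 248 ± 11 CPM (adjusted p = 5.97e-41, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The antiviral gene Oasl2 fell by 2.89 on the log2 scale (adjusted p = 1.98e-42), and the MHC class II chain Cd74 rose by 1.90 ± 0.08. Per2 rose by 0.78 ± 0.09 and Nr1d1 fell by 0.86, while no change was called in Arntl, at -0.20 ± 0.10 (adjusted p = 0.0815), or Dbp, at -0.12 ± 0.20 (adjusted p = 0.571). Arntl was called lower without con replicate 1 (-0.25, adjusted p = 0.0493) or without BSF_C replicate 1 (-0.26, adjusted p = 0.0392). Interferon-stimulated genes fell in 37 and rose in 2 of 46 (camera, adjusted p = 1.2e-12, 0.0279 with an estimated correlation), lipid absorption genes rose in 30 and fell in 1 of 32 (1.64e-11, 0.025 with an estimated correlation), and MHC class II genes rose in 7 of 8 (0.00384, 0.0585 with an estimated correlation). These counts were unchanged when adjusted over the list alone. Leukocyte markers rose in 21 and fell in 6 of 30 (0.0224, 0.135 with an estimated correlation). Neural and glial genes rose in 7 of 10 (0.0361, 0.124 with an estimated correlation), and this list did not pass without con replicate 3 (0.0536). The test called 10444 genes, 5695 higher and 4749 lower, with 4147 at least 2-fold changed. Of the lists, 19 passed upward and 6 downward, 5 of the 25 with an estimated correlation.

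LSF against con asks how lunch skipping differed from the control group, with the same limit of a possible con batch. Pck1, which makes phosphoenolpyruvate for new glucose (chromosome 2, 173153048 to 173159273), rose from 15.3 ± 1.23 to 489 ± 5.70 CPM (SD, n = 3 and 3), by 4.99 ± 0.08 on the log2 scale (SE; adjusted p = 1.97e-47, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cyp3a11, a bile acid and drug oxidase with close paralogs, rose from 0.583 ± 0.358 to 723 ± 25.6 CPM (10.26 ± 0.14), and Pdk4, which holds back pyruvate oxidation, rose by 3.76 ± 0.12. The con mean of Cyp3a11 lay below 3 counts in a single con library (0.619 to 0.691 CPM), so its SE understates the counting error. The amino acid transporter Slc6a19 rose by 2.83 ± 0.06 and Apoa4 by 3.86 ± 0.05. Olfm4, a stem cell marker, fell by 1.11 on the log2 scale and the cyclin Ccna2 by 1.20. Oasl2 fell by 1.88 and Egr1 by 1.97, and Cd74 rose by 0.79 ± 0.08. Among clock genes, Per2 rose by 0.48 ± 0.09 (adjusted p = 5.7e-06). Nr1d1 was called higher by 0.22 ± 0.07 (adjusted p = 0.00851) but not without con replicate 1 (0.15, adjusted p = 0.091) or LSF replicate 1 (0.18, adjusted p = 0.0556). Dbp was called higher by 0.47 ± 0.18 (adjusted p = 0.0198) but not without con replicate 1 (0.32, adjusted p = 0.151), con replicate 2 (0.45, adjusted p = 0.0517) or LSF replicate 3 (0.39, adjusted p = 0.0896), nor with GC and length trends removed (0.27, adjusted p = 0.176). Arntl was at -0.12 ± 0.10 (adjusted p = 0.279).

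By list in LSF, xenobiotic metabolism genes rose in 39 and fell in 1 of 41 (camera, adjusted p = 1.74e-15, 0.0145 with an estimated correlation), and peptide digestion genes rose in 24 and fell in 1 of 26 (7.55e-12, 0.0258 with an estimated correlation). Fatty acid oxidation and PPARA target genes rose in 31 and fell in 5 of 38 (1.62e-06, 0.0392 with an estimated correlation), and stem cell genes fell in 16 and rose in 1 of 18 (2.67e-06, 0.0292 with an estimated correlation). Cholesterol synthesis genes fell in 18 and rose in 1 of 25, 19 lower when adjusted over the list alone (5.3e-06, 0.0326 with an estimated correlation). Interferon-stimulated genes fell in 30 and rose in 7 of 46 (3.72e-06, 0.0738 with an estimated correlation), proliferation genes fell in 23 and rose in 5 of 36 (0.0036, 0.0577 with an estimated correlation) and all 8 bile acid genes rose (0.00679, 0.0672 with an estimated correlation). MHC class II genes rose in 7 of 8 (0.0498, 0.132 with an estimated correlation), a list that did not pass without con replicate 2 (0.0579), con replicate 3 (0.0521) or LSF replicate 3 (0.055), and leukocyte markers rose in 21 and fell in 6 of 30 (0.00639, 0.1 with an estimated correlation). Immediate early genes fell in 16 and rose in 9 of 30 (0.0404, 0.348 with an estimated correlation) and did not pass without con replicate 2 (0.0547). The unfolded protein, villus bottom, antimicrobial, NF-kB, acinar and amino acid response lists, whose median, mean and test differed in sign, did not pass. The test called 10293 genes, 5569 higher and 4724 lower, with 4249 at least 2-fold changed, and 19 lists passed upward and 6 downward, 7 of the 25 with an estimated correlation.

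DSF against con asks how dinner skipping differed from the control group, again with the limit of a possible con batch. Apoa4 rose by 3.26 ± 0.05 (log2, SE; n = 2 and 3) to 9381 ± 133 CPM, and Lct by 3.25 ± 0.06. Gstm3, a glutathione transferase with close relatives, rose by 3.30 ± 0.07, and Reg3g, an antibacterial lectin of the epithelium (chromosome 6, 78466269 to 78468872), rose from 332 ± 13.8 to 760 ± 29.2 CPM (1.20 ± 0.06, adjusted p = 1.1e-25, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cd74 rose by 1.93 ± 0.08, while Oasl2 fell by 1.88, Duox2 by 2.7 and Egr1 by 2.32. Nr1d1 fell by 0.57 on the log2 scale (adjusted p = 1.23e-07). No change was called in Per2, at -0.05 ± 0.11 (adjusted p = 0.702), Arntl, at -0.14 ± 0.11 (adjusted p = 0.293), or Dbp, at -0.04 ± 0.22 (adjusted p = 0.863). Ribosomal protein genes rose in 67 and fell in 2 of 79 (camera, adjusted p = 8.89e-14, 0.124 with an estimated correlation), and lipid absorption genes rose in 29 and fell in 1 of 32, 30 higher when adjusted over the list alone (1.6e-12, 0.0215 with an estimated correlation). Interferon-stimulated genes fell in 31 and rose in 7 of 46 (2e-06, 0.0688 with an estimated correlation), and MHC class II genes rose in 7 of 8 (0.00535, 0.0611 with an estimated correlation) beside leukocyte markers, which rose in 21 and fell in 6 of 30 (0.00263, 0.0731 with an estimated correlation). The bile acid list (0.044, 0.124 with an estimated correlation) did not pass without DSF replicate S2 (0.0577), nor did the heat shock list (0.0361, then 0.0589; 0.124 with an estimated correlation), and the mitochondrially encoded list (0.0486, 0.536 with an estimated correlation) did not pass without con replicate 2 (0.0869). The test called 9677 genes, 5227 higher and 4450 lower, with 3744 at least 2-fold changed, and 20 lists passed upward and 6 downward, 6 of the 26 with an estimated correlation.

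The 4 comparisons with con shared its 3 libraries and so their chance values. In all 4, 4276 genes were called higher and 3768 lower, Apoa4 and Lct among the first and Oasl2 and Egr1 among the second. Pearson's r of log2 fold changes across the 14300 genes, which are not independent replicates, was 0.958 to 0.987 for the 6 pairs. It was 0.521 to 0.655 for simulated unchanged groups that shared a con group drawn anew. The covariance was 3.203 to 3.384 against a simulated 0.1 to 0.105. Pairs shared 4625 to 5177 higher calls against 2000 to 2218 for independent lists of the same sizes, and 4030 to 4353 lower calls against 1422 to 1569. Simulated unchanged groups shared 0.05 to 0.1 calls. In the simulation all libraries, con included, were drawn from the con means, with the same spread per gene in every group. The real con pairs varied more than pairs of other groups, and no shift of con alone was drawn. The simulation therefore cannot tell the excess from a batch of con. The 3 con libraries were too few to divide, and part of the excess may come from the shared controls.

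The comparison of BSF_C with BSF asks how the combined group differed from breakfast skipping. No difference was called in 8 genes followed in every comparison. Cd74 was at 0.06 ± 0.07 (log2, SE; n = 3 and 2), Per2 at -0.10 ± 0.08, Nr1d1 at 0.01 ± 0.09, Arntl at -0.23 ± 0.10, Dbp at -0.03 ± 0.20, H2-Ab1, an MHC class II beta chain, at 0.07 ± 0.11, Epcam at 0.07 ± 0.06 and Ptprc at 0.21 ± 0.16, each with an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ccn2, a matrix protein of fibroblasts, rose from 1.69 ± 0.293 CPM in BSF to 27.8 ± 5.45 CPM in BSF_C (4.01 ± 0.55, adjusted p = 1.28e-05). The collagen gene Col1a1 rose by 2.61 ± 0.42 and the kidney injury gene Havcr1 by 3.53 ± 0.57, while Gpnmb, a melanosome glycoprotein, fell by 1.31 on the log2 scale (adjusted p = 1.28e-05). Means in LSF and DSF also lay above BSF, at 30.5 and 18.7 CPM for Ccn2 and 13.9 and 8.76 CPM for Col1a1. For Havcr1 they were 3.48 and 3 CPM, against 0.515 in BSF. Gpnmb was lower in BSF_C (11.2 CPM) than in BSF, LSF and DSF (27.5, 29.1 and 25.5 CPM). In these 4 genes all 3 BSF_C libraries lay on the same side of both BSF libraries, as the rule that named them required. Havcr1 was not called without BSF replicate 2 (2.82). DESeq2 called none of the 4, with Ccn2 at 4.04 (adjusted p = 0.15), Col1a1 at 2.62 (0.551), Havcr1 at 3.52 (1) and Gpnmb at -1.30 (0.385). Limma-voom called only Gpnmb, with Ccn2 at 3.97 (0.517), Col1a1 at 2.47 (0.369) and Havcr1 at 3.59 (0.177). By the same test 19 genes were called, 15 higher and 4 lower, 17 of them at least 2-fold changed, and 573 of 14300 had an unadjusted p under 0.05. Of the 19, 17 belonged to the melanocyte, kidney tubule or fibroblast lists, which were written after the data were examined: 14 higher and 3 lower. The other 2 were Gask1b, a kinase-like Golgi protein (-1.15 ± 0.26, adjusted p = 0.0383), and Ptgs2, a prostaglandin synthase (adjusted p = 0.0417). Ptgs2 had only 2 counts in the BSF libraries together and 40 in those of BSF_C, a ratio of 13.2 with an exact 95% counting interval of 3.42 to 113. Gask1b was not called without BSF_C replicate 2 (-1.22), BSF_C replicate 3 (-0.87), BSF replicate 1 (-1.30) or BSF replicate 2 (-0.97), and Ptgs2 was not called without any single library of these 5 (adjusted p = 0.0548 to 1). Neither was called by DESeq2 (adjusted p = 0.364 for Gask1b, at -1.15, and 0.927 for Ptgs2) or limma-voom (adjusted p = 0.185 for both, with Gask1b at -1.23). The count was 12 without BSF_C replicate 2, 13 without BSF replicate 1 and 14 without BSF replicate 2.

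By list, 7 of 43 passed in BSF_C against BSF with the preset correlation, 5 upward and 2 downward, and none with an estimated correlation. In fry, a test of each list on its own, 1 list of 43 passed, which was none of these 7. Ribosomal protein genes had a median log2 fold change of 0.061 with none of 79 called (camera, adjusted p = 5.35e-06, 0.321 with an estimated correlation; 0.699 without BSF replicate 2). Stromal genes (1.04e-05, 0.0672 with an estimated correlation) rose in 2 of 23. Immediate early genes (0.00107, 0.144 with an estimated correlation) included Ccn1, a matrix protein, which rose by 1.30 ± 0.22 but was not called without BSF replicate 2 (1.12, adjusted p = 0.249), by DESeq2 (1.29, adjusted p = 0.634) or by limma-voom (1.30, adjusted p = 0.0844). The Paneth cell list (0.00444, 0.187 with an estimated correlation) did not pass without BSF replicate 2 (0.151). Interferon-stimulated genes were lower as a list (0.012, 0.275 with an estimated correlation) with none of 46 called, and did not pass without BSF_C replicate 1 (0.169) or BSF replicate 2 (0.269). The NF-kB list (0.0474, 0.187 with an estimated correlation) did not pass without BSF_C replicate 2 (0.242), BSF replicate 1 (0.0669) or BSF replicate 2 (0.239), and neural and glial genes, lower as a list (0.0497, 0.142 with an estimated correlation), did not pass without BSF_C replicate 2 (0.342), BSF replicate 1 (0.119) or BSF replicate 2 (0.101).

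BSF against the mean of LSF and DSF asks what breakfast skipping had that skipping another meal had not. No con mean enters it, although con libraries took part in the fit that set the spread. Heart muscle genes summed to 408.5 to 473.5 CPM in the BSF and BSF_C libraries and to 918.7 to 1053 CPM in those of LSF and DSF. The labels give no batch, so a batch that divides these groups cannot be told apart from the skipped meal. Cyp1a1 rose by 2.07 ± 0.06 (log2, SE; adjusted p = 1.52e-32, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 247 ± 14.7 CPM in BSF (SD, n = 2) against 71.9 ± 4.82 in LSF (n = 3) and 48.0 ± 0.17 in DSF (n = 2). Other detoxifying genes fell, the glutathione transferase Gstm1 by 1.34 and its relative Gstm3 by 1.06 on the log2 scale, 2 genes close enough in sequence to share reads. Of 41 xenobiotic metabolism genes, 20 fell and 1 rose, 21 lower when adjusted over the list alone (camera, adjusted p = 4.99e-12, 0.0145 with an estimated correlation). The median log2 fold change of this list against con was 1.27 in BSF, 1.65 in LSF and 1.25 in DSF, so its level in BSF lay between those of the groups averaged. Oasl2 fell by 1.06 (adjusted p = 2.96e-19) and the antiviral gene Ifit3 by 1.24, and of 46 interferon-stimulated genes 36 fell and none rose, 37 lower when adjusted over the list alone (2.68e-24, 0.0145 with an estimated correlation). Pck1 fell by 1.69 (adjusted p = 1.2e-26), at 57.3 ± 4 CPM in BSF against 489 ± 5.70 in LSF and 70.3 ± 1.15 in DSF. The amino acid transporter Slc6a19 fell by 0.67 and Slc15a1, the intestinal peptide transporter, by 0.76, and of 26 peptide digestion genes 21 fell and none rose (6.81e-16, 0.0175 with an estimated correlation). The medians of this list against con were 0.84 in BSF, 1.31 in LSF and 0.93 in DSF, so BSF lay nearer to DSF than to LSF. Egr1 fell by 1.26, with 22 of 30 immediate early genes lower and 3 higher (8.38e-17, 0.0183 with an estimated correlation). In the genes named here both BSF libraries lay on the same side of the 5 LSF and DSF libraries. The naming rule favours this, as it took genes without overlap or with the smallest p of a list.

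Clock, growth and stress genes also differed in this comparison. Per2 rose by 0.66 ± 0.08 (log2, SE; adjusted p = 2.8e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Nr1d1 fell by 0.68 (adjusted p = 3.34e-09), with no call in Arntl, at 0.17 ± 0.10 (adjusted p = 0.221), or Dbp, at -0.31 ± 0.18 (adjusted p = 0.22). The list of Bmal1-phase clock genes passed upward with 2 higher and 1 lower of 7 (camera, adjusted p = 0.0185, 0.0903 with an estimated correlation), although its median against con was lowest in BSF (0.04, against 0.33 in LSF and 0.19 in DSF), and the list of Per and Rev-erb genes did not (0.594). Hspa5, the chaperone BiP, rose by 0.41 ± 0.05, and 12 of 22 unfolded protein response genes rose, 13 when adjusted over the list alone, and none fell (1.24e-06, 0.0153 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose by 0.54 ± 0.08, and 11 of 36 proliferation genes rose, 15 when adjusted over the list alone, and none fell (2.17e-06, 0.0183 with an estimated correlation). Cd74 rose by 0.48 ± 0.06 (adjusted p = 5.42e-08), at 134 CPM in BSF against 64.9 in LSF and 143 in DSF, so its level in BSF lay between those of the groups averaged. MHC class II genes rose in 4 of 8 (0.00259, 0.0536 with an estimated correlation), with medians against con of 1.61 in BSF, 0.79 in LSF and 1.67 in DSF, while leukocyte markers fell in 16 of 30, 17 when adjusted over the list alone (7.46e-08, 0.0215 with an estimated correlation). Ptprc fell by 0.40 ± 0.15 (adjusted p = 0.0432), a call lost without BSF replicate 1 (-0.30), BSF replicate 2 (-0.51), DSF replicate S3 (-0.34), LSF replicate 2 (-0.40) or LSF replicate 3 (-0.37), by DESeq2 (-0.41), with library totals alone (-0.35) or with thinned libraries (-0.44), and Epcam was at -0.05 ± 0.06 (adjusted p = 0.536). H2-Ab1 rose by 0.35 ± 0.10 (adjusted p = 0.00887), a call lost without BSF replicate 1 (0.37), BSF replicate 2 (0.32) or DSF replicate S3 (0.28), or with thinned libraries (0.24).

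Transcripts of other tissues differed here too. Of 27 heart muscle genes 21 fell and none rose, of 21 brain genes 15 rose and none fell, and all 16 fibroblast and matrix genes fell. The fibroblast and matrix sum was 40.4 CPM in BSF but 158 CPM in BSF_C, near the 164 CPM of DSF. Intraepithelial lymphocyte genes fell in 7 of 9, gut smooth muscle genes in 3 of 5 and kidney tubule genes in 3 of 12, and none rose. Enteric neuron and glia genes rose in 4 of 7 and none fell. No melanocyte, skin keratinocyte or hepatocyte gene was called. Ccn2 fell by 3.79, although it ranged widely between libraries (30.5 ± 21.5 CPM in LSF, 18.7 ± 19.6 in DSF), and Gad1, which makes the neurotransmitter GABA, rose by 1.89 ± 0.29. Stromal genes fell in 15 of 23 (camera, adjusted p = 4.1e-08, 0.0404 with an estimated correlation), and neural and glial genes rose in 7 of 10 (9.39e-05, 0.0292 with an estimated correlation). The heat shock list passed upward (0.0278, 0.124 with an estimated correlation) with a median of 0.133 and a mean of -0.004, and did not pass without BSF replicate 1 (0.0637) or DSF replicate S3 (0.0647). Passing was lost without BSF replicate 2 for Btnl genes (0.0153, then 0.0553; 0.124 with an estimated correlation), without DSF replicate S2 for TCA cycle genes (0.0225, then 0.0575; 0.387 with an estimated correlation), and without BSF replicate 1 (0.0854) or DSF replicate S3 (0.0664) for cholesterol synthesis genes (0.0418, 0.209 with an estimated correlation). Medians against con in BSF, LSF and DSF were 0.26, 0.25 and 0.27 for the TCA cycle and -0.51, -0.72 and -0.44 for cholesterol synthesis, so BSF lay between the groups averaged. It was also lost for erythroid genes (0.0459, 0.209 with an estimated correlation) without BSF replicate 1 (0.0629) or DSF replicate S2 (0.0742), and for ribosomal protein genes (0.0494, 0.63 with an estimated correlation) without BSF replicate 2 (0.879), DSF replicate S2 (0.301), LSF replicate 1 (0.0746) or LSF replicate 3 (0.0684). The test called 3055 genes, 1411 higher and 1644 lower, or 46.2% higher, and 60.9% of the calls were higher when libraries were scaled to their totals alone. At least 2-fold changes were 715. The count was 1467 without BSF replicate 1 and 1478 without BSF replicate 2. Of the lists, 11 passed upward and 20 downward, 12 of the 31 with an estimated correlation.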

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

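Library totals alone, thinned libraries, GC and length trends removed, non-epithelial lists left out, con left out of the fit and every alternative for LSF against DSF were chosen only after the results were seen. Of 12896 recomputed values for named genes, 12645 kept their direction and their side of the threshold, 203 lost a call, 14 gained one and 34 reversed. Most of these genes were picked from the same libraries for large changes or small p, which favours kept calls. Of 1342 for lists, 1188 kept both and 154 no longer passed, 109 of these with an estimated correlation, and no list that passed changed the sign of its median under either other scaling. Of 195 counts and correlations, 166 stayed within 1.5 times the count or within the spread. Requiring a log2 fold change of at least 1 left 4112 genes for BSF, 4147 for BSF_C, 4249 for LSF and 3744 for DSF against con, 715 for BSF against the mean of LSF and DSF and 203 for LSF against DSF, by construction. Other counts against con ranged from 8319 to 11025. For BSF_C against BSF, edgeR called 19, DESeq2 2 and limma-voom 4; edgeR called 30 with no filter on low counts, 32 with only the groups compared, 29 with con libraries left out of the fit, and 12 to 23 when each BSF or BSF_C library was left out. With non-epithelial lists left out, edgeR called 0, with 555 genes at an unadjusted p under 0.05: those lists hold 17 of the 19, and Gask1b, still at -1.15, and Ptgs2 had an adjusted p of 0.15 each. Beyond those 17, the cause was not tested. Leaving out a library of the groups compared gave 1467 to 2748 genes for BSF against the mean of LSF and DSF, lowest without BSF replicate 1 and 1478 without BSF replicate 2, and 1288 to 1866 for LSF against DSF, lowest without DSF replicate S2 and 1430 without DSF replicate S3; a group of 1 library was then assumed to vary like the others. Leaving out a con library gave 22 to 27 genes for BSF_C against BSF, 3143 to 3750 for BSF against the mean of LSF and DSF and 2317 to 2776 for LSF against DSF, and all con libraries 3969 and 2947 for the last 2. With an estimated correlation, camera passed 6, 5, 7 and 6 lists for BSF, BSF_C, LSF and DSF against con, 0 for BSF_C against BSF and 12 for BSF against the mean of LSF and DSF. Fry, which does not compare a list with other genes, passed 39 lists for BSF, 40 for BSF_C and 40 for LSF against con, and 1 for BSF_C against BSF. The mean correlation of fold changes was 0.968, 0.957 by limma-voom and 0.584 for simulated unchanged groups. The replicate block gave 9729, 10284 and 10136 genes for BSF, BSF_C and LSF against con and 18 for BSF_C against BSF, and 25, 25, 24 and 8 lists; of the 19 genes of BSF_C against BSF 16 stayed called, without Gask1b, Ptgs2 and Cyp24a1, Bgn and Zc3h7a were gained (the last 3 named after their values were seen), and the NF-kB list there and the MHC class II list in LSF no longer passed. The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.148 to 0.083, 0 of 15 pairs over 0.1, and 2 of 11 libraries matched their own number best. The DSF libraries had no replicate number and were left out of the block. Directions reversed for genes near 0. In Arntl these were BSF against con without con replicate 1 (-0.01 to 0.06 over libraries left out), GC and length trends removed (0.06 in BSF_C, 0.14 in LSF and 0.13 in DSF against con), library totals only (0.02 in DSF), and LSF against DSF (-0.03 to 0.05 over libraries left out, -0.05 thinned and -0.05 with totals only). In Dbp they were -0.25 to 0.09 for BSF, -0.28 to 0.06 for BSF_C and -0.20 to 0.14 for DSF against con and -0.14 to 0.08 for BSF_C against BSF over libraries left out, totals only (0.08, 0.04 and 0.11 for BSF, BSF_C and DSF) and thinned libraries (0.04 for DSF, 0.12 for BSF_C against BSF). Per2 in DSF against con was -0.11 to 0.01 over libraries left out, 0.11 with totals only, 0.04 thinned and 0.21 with GC and length trends removed. Nr1d1 in BSF_C against BSF was -0.04 to 0.07 over libraries left out, -0.02 with the replicate block, -0.12 thinned and -0.03 with GC and length trends removed. Over libraries left out, H2-Ab1 in BSF_C against BSF was -0.06 to 0.17 and Ptprc in LSF against DSF -0.04 to 0.17. Alas2 was -0.09 thinned in BSF against the mean of LSF and DSF, and Bhlhe40, called lower in DSF against con at -0.24, was 0.01 with GC and length trends removed and no longer called; for these reversals the cause was not tested. Depth limits genes near 3 counts in a group, whose folds are bounds with no count and ratios with wide intervals at 1 to 3 counts.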

Other observations

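The counts under other splits of the samples were planned, but how to read them was written only after the results were seen, and the comparison of LSF with DSF and all other tests in this part were chosen only then. LSF against DSF asks how the positions of the skipped meal differ without a con mean, although con libraries took part in the fit. Pck1, which makes phosphoenolpyruvate for new glucose, was higher in LSF by 2.80 ± 0.07 (log2, SE; n = 3 and 2; adjusted p = 5.76e-37, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The oxidase Cyp3a11 was higher by 2.02 ± 0.06, and Slc2a5, the fructose transporter, by 1.12 ± 0.09. Reg3g, an antibacterial lectin, was lower in LSF by 1.36 on the log2 scale (-1.36 ± 0.06, adjusted p = 3.97e-27), the oxidase Duox2 was at -1.99 ± 0.12, Nos2, which makes nitric oxide, at -1.99 ± 0.32, and Cd74, the MHC class II chain, at -1.14 ± 0.07. Nr1d1, a repressor of the clock, was higher in LSF by 0.79 ± 0.08 and Per2 by 0.53 ± 0.09. In each of these genes all 3 LSF libraries lay on the same side of both DSF libraries. Apart from Cd74, Nr1d1 and Per2, followed in every comparison, they were named by a rule that favours such separation. Of 16 genes for carbohydrate digestion and sugar transport 15 were higher in LSF (camera, adjusted p = 8.39e-24, 0.000927 with an estimated correlation), of 41 xenobiotic metabolism genes 29 were higher and 1 lower, 31 and 1 adjusted over the list alone (1.33e-29, 0.00044 with an estimated correlation), and of 38 fatty acid oxidation and PPARA target genes 22 were higher, 23 adjusted over the list alone (3.62e-19, 0.000927 with an estimated correlation). Antimicrobial genes were lower in 12 and higher in 1 of 22, 14 and 1 adjusted over the list alone (1.05e-12, 0.00173 with an estimated correlation), proliferation genes lower in 21 of 36, 28 adjusted over the list alone (2.61e-12, 0.000927 with an estimated correlation), and cholesterol synthesis genes lower in 17 of 25, 20 adjusted over the list alone (6.65e-12, 0.00207 with an estimated correlation). Leukocyte markers differed in 2 of 30, 1 in each direction (adjusted p = 0.87). Other tissues differed in part: fibroblast and matrix genes were higher in 4 and lower in none of 16, brain genes higher in 3 and lower in none of 21, and erythroid genes higher in 2 of 3 (median 1.34, adjusted p = 0.00631, 0.0787 with an estimated correlation).

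The test called 2271 genes in LSF against DSF, 1283 higher and 988 lower, or 56.5% higher, and 38.0% of the calls were higher when libraries were scaled to their totals alone. It called 1288 without DSF replicate S2 and 1430 without DSF replicate S3. At least 2-fold changes were 203. Of the lists, 15 passed upward and 10 downward, 19 of the 25 with an estimated correlation.

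The 6 libraries of BSF_C and con can be split in 10 ways, too few for a share under 0.05: the real split gave 10444 called genes, the highest of the others 0, and 1 of the 10 splits, the real one, gave as many. For LSF and con the real split gave 10293, the highest of the others 0, and again 1 of 10 gave as many.

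The con libraries stood apart from the other 10 in totals, in genes with a count and in most calls. Smaller totals do not account for the calls, since at least 9008 genes were called in each comparison with con after all libraries were thinned to 1 total, and GC and gene length trends do not account for most of them, since 85.6% to 88.9% of the called genes stayed called with the trends removed. Keratinocyte transcripts were 157 times higher in the lowest con library than in the highest other library, and Eif3f, a subunit of a translation initiation complex picked after its values were seen, was at 9.76 ± 0.696 CPM in con against 153 to 183 CPM elsewhere, where Eif3l of the same complex was at 62.9 ± 3.26 against 62.7 to 75.9 CPM. The con libraries may therefore have been prepared or sequenced apart from the rest, which cannot be told apart from feeding because con alone would make up that batch. Feeding stays open as an untested explanation for any gene called against con.

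Heart and brain transcripts were present in the 10 libraries that are not con, although a sort on EpCAM would remove such cells; Pln, Myh6 and Mb of heart were at 72.6, 56.4 and 41.3 CPM in BSF and at most 0.0688 CPM in con. Gut smooth muscle as the source of the heart transcripts is argued against, since Acta2, Actg2 and Myh11 together had at most 0.0482 times the counts of Myh6. A single source holding both in a fixed proportion is argued against too. The values are for 13 heart and 11 brain genes with at most 3 counts in con and at least 5 CPM elsewhere. From BSF to LSF the heart genes moved by a median log2 of 1.35 (SD 0.39). The brain genes moved by -1.16 (SD 0.56), 2.51 apart. Both lists were written after the values were seen, and a source whose heart and brain content varied is not addressed. Heart RNA or reads added in different amounts remain a candidate explanation, as the 13 genes moved together with an SD of 0.39, though their list too was written after the values were seen, and their origin was not tested, nor was enteric nerve as a source of the brain transcripts. No biological explanation was tested.

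Few genes were called between BSF_C and BSF. Of 14281 genes not called, 554 (3.88%) had an unadjusted p under 0.05, but 6.09% did with con libraries left out of the fit and 5.67% with only the groups compared, so small differences beyond the 19 called genes stay open. Unequal amounts of melanocyte, kidney tubule and fibroblast RNA also stay open: 19 of 20 uncalled genes moved as the called ones of their list, which decides nothing since these lists were written after the values were seen. Whether the control component of BSF_C acts on these cells was not tested, since its meaning was not given.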
